A study of Mus musculus with 12 samples.

How the data were processed

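Gene expression was measured on 12 Illumina bead arrays, 6 of WT and 6 of Terc-/- mouse leukaemia stem cells. Terc encodes the RNA component of telomerase, and MLL-AF9 is a fusion oncogene of human acute myeloid leukaemia. Per the labels, recipients irradiated with 5.5 Gy at 6 to 8 weeks of age received 10000 bone marrow progenitors that expressed MLL-AF9 with green fluorescent protein, either WT or G3 Terc-/-. Stem cells were later sorted from the recipients' bone marrow as fluorescent, lineage-negative, Kit-positive and Fcgr-positive cells when each leukaemia appeared. The labels add a phosphorylation status to the Terc-/- arrays. It is p-p53 (Ser15) on 3 arrays, p-Foxo3a (Ser253) on 2 arrays and not given on replicate 5. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure the spread between these samples. The number of samples limits the precision of these values.

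The values analysed were the authors' deposited log2 values of 38502 probes. GenomeStudio is named in the submitters' processing notes, and its version, the normalization and the background treatment are not given in the sources used here. From the values themselves, sorted log2 values differed by at most 0.09 between arrays at any rank, as quantile normalization gives. Array medians lay between 6.57 and 6.58, and genes were not centred. The log base was read from this range and is stated in no source. No background subtraction was visible, so fold changes on this scale understate changes, most of all for dim genes. A deposited table of raw signals and detection p-values names its columns in a way that matches no sample. Its 24 columns (12 signal and 12 detection columns) were used in no step. For this reason the planned background correction from detection p-values was replaced by limma on the deposited log2 values.

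A background limit took the place of detection p-values. The mode of all values was 6.35, the spread on its lower side gave an SD of 0.13, and the limit of 6.57 leaves 5% of such background above it (a tail p of 0.05). A probe was kept when it lay above the limit on at least 3 of 12 arrays, which 21915 probes did. The platform annotation gave 1 gene to 32034 probes and several genes to 16, and did not list 6452. Symbols were checked through Entrez identifiers against the gene table of GRCm38.p6, which 31976 annotated probes matched. That table was also used for the order of genes along chromosomes. The brightest kept probe, chosen over all arrays without the groups, stood for each of 11889 genes. Where a gene was below the limit in every sample of 1 group, a bound was computed in place of a fold, from the bright group's mean and, per sample of the dim group, the higher of the limit and the gene's own value.

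The arrays of WT replicates 5 and 6, and those of Terc-/- replicates 2 and 6, were nearly identical. Their correlations over probes were at least 0.996, against at most 0.990 in the other array pairs (66 pairs in all). No kept probe differed 2-fold within these pairs, against 281 to 1598 probes in other pairs. The SD of differences of bright probes, estimated from the median absolute deviation, was at most 0.138 in these pairs and at least 0.241 in others. For background probes, which are of another brightness, its median over all pairs was 0.151. Each such pair was averaged and counted as 1 sample, before any group was tested. This left 5 WT samples and 5 Terc-/- samples, of which 2 were p-p53 (replicate 3 and the averaged replicates 2 and 6), 2 were p-Foxo3a (replicates 1 and 4) and 1 had no status. The design fixed before the data were examined counted 12 arrays, and counts with all arrays as separate samples are given among the alternatives.

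Terc-/- and WT samples were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, all tests two-sided. The p-p53 and p-Foxo3a samples were compared with WT and with each other in a fit of 3 levels over 9 samples, without replicate 5. For each comparison, 30 gene lists with at least 5 measured members, fixed before the data were examined, were tested with camera of limma at its preset correlation of 0.01. Of these, 10 hold markers of cell types and 20 hold pathways or target genes. Camera was repeated with an estimated correlation, and fry was run beside it. Between the 5 Terc-/- and 5 WT samples, mean deviations of each list from the genes' overall means were compared by an exact permutation test over 252 arrangements, whose smallest p is 0.00794. The genes named are the 24 of largest change among those past the threshold or, where fewer pass, those of smallest p, and 12 genes fixed in advance. Genes outside this rule are said to have been chosen after their values were seen, and members of lists are shown by their rank within the list.

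The fits were tested on simulated data with the spread of the real samples over the same 11889 genes. Noise was independent between genes, and each round held 100 genes changed by 1 and 100 changed by 2. With fewer changed genes the adjustment is stricter, so the shares recovered do not carry over to a comparison with few changes. With 5 against 5 samples, limma recovered 85.2% of genes changed by 1 on the log2 scale and 97.2% of those changed by 2. For p-p53 against WT it recovered 68.4% and 92.4%, for p-Foxo3a against WT 69.9% and 92.8%, and for p-p53 against p-Foxo3a 55.1% and 89.4%. A list shifted by 0.3 was found in 20 of 20 rounds of the Terc-/- against WT comparison, with 1 other list called over all rounds. Noise in these rounds was independent between genes, whereas the estimated correlation in the real samples was 0.52 for G2/M and mitosis genes. These rounds therefore do not show how often camera calls unchanged lists in the real samples. A scan of chromosomes used the 7068 genes with a mean of at least 7.5, clipped their deviations from the gene's median over samples at 1, and took medians per chromosome and in windows of 50 neighbouring genes. A simulated shift of 0.4 gave medians of at least 0.34 on the shifted chromosome and of at most 0.06 elsewhere.

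Alternatives covered the filter on dim probes (with stricter filters on 6 arrays and at 0.01 set from the background limit), the choice of probe, the variance model, array weights, the replicate number as a block, the list test and leaving out each array. Cyclic loess, normexp with an offset of 50 on the deposited values, the 12 arrays as separate samples, the omission of both arrays of a near-identical pair and the omission of 4 chromosomes were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.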

Results

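Expression of 11889 genes was compared between 5 WT and 5 Terc-/- samples of MLL-AF9 leukaemia stem cells, of which 2 Terc-/- samples carried the p-p53 label, 2 the p-Foxo3a label and 1 no status. Each array had between 19248 and 19432 of its probes above the background limit. WT replicates 5 and 6 were nearly identical and were counted as 1 sample, as were Terc-/- replicates 2 and 6. No probe in the annotation used here carries the symbols Terc, Trp53, Fcgr3 or Ddx3y, and Tert was not above background on enough arrays, so these values do not check the knockout. Values are log2 units, and differences are Terc-/- minus WT unless stated.

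Terc-/- and WT samples were compared to ask which genes and pathways differ in leukaemia stem cells without telomerase RNA. Phlda3, a p53 target that restrains Akt signalling, averaged 7.56 ± 0.41 (SD, n = 5) in Terc-/- and 6.54 ± 0.17 (SD, n = 5) in WT samples. This is a difference of 1.02 ± 0.18 (SE), or 2.03-fold, with Phlda3 above background in 2 of 5 WT samples. Dennd5b (1.46 ± 0.29, SE) and Ntng2 (1.07 ± 0.20) were also higher in every Terc-/- sample than in any WT sample. Several genes of DNA replication and repair had lower means in Terc-/- samples, among them the replicative helicase components Gins3 (-0.56 ± 0.12) and Cdc45 (-0.33 ± 0.06), the Brca1-associated helicase Brip1 (-0.57 ± 0.12) and the checkpoint kinase Chek2 (-0.51 ± 0.12). The centriole protein Cep295 was 1.62-fold lower (-0.70 ± 0.12).

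No gene passed the threshold in limma (smallest adjusted p = 0.502), while 883 genes had an unadjusted p under 0.05 (331 higher and 552 lower in Terc-/-), against 594 expected by chance. Of the 24 named genes, 9 had higher and 15 lower means, by 0.33 to 1.46, and in 21 of them the groups did not overlap. These genes were chosen for small p in this comparison, so their separation follows largely from the choice. Over all genes the groups did not overlap for 141 (41 higher and 100 lower in Terc-/-), 1.19% against 0.794% by chance. That count was not set against other splits of the samples. Without Terc-/- replicate 3, whose Phlda3 value of 6.85 was the lowest in its group, 1 gene passed, Phlda3 (1.20, adjusted p = 0.00825).

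**Figure D1:**
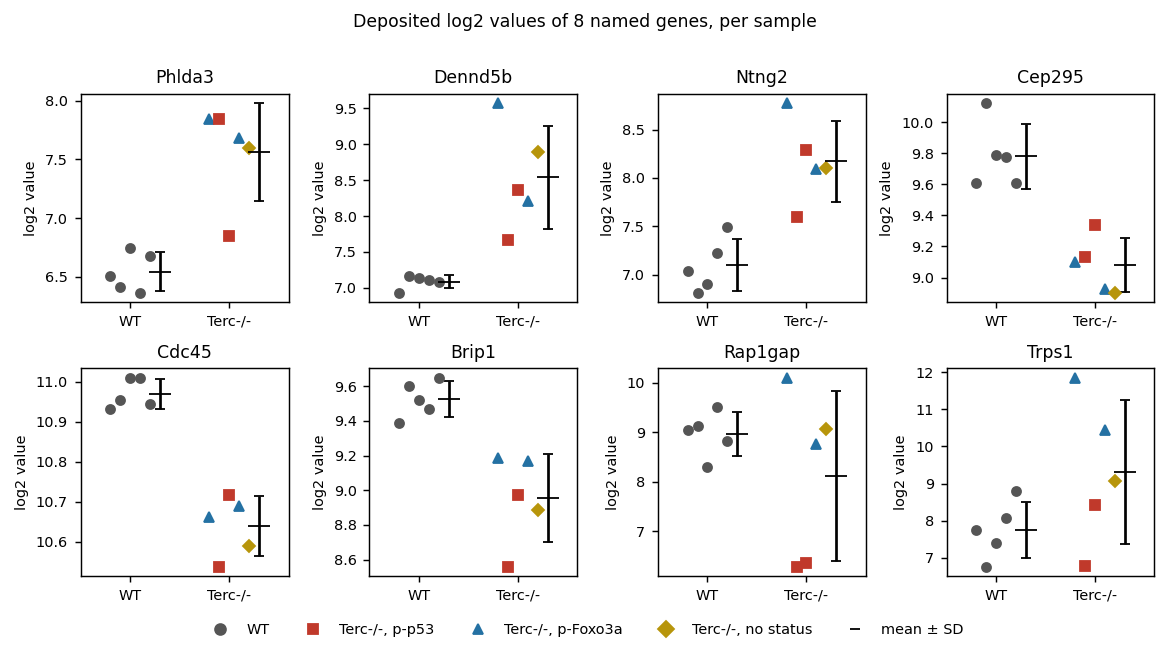
Log2 values of 8 named genes in each sample, by group on the horizontal axis, with symbols for the labelled phosphorylation status and bars for the mean and SD of the group. Phlda3, Dennd5b, Ntng2, Cep295, Cdc45 and Brip1 separate the 5 Terc-/- from the 5 WT samples, whereas Rap1gap is low in the 2 p-p53 samples and Trps1 is highest in the 2 p-Foxo3a samples.

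Genes of the interferon response rose as a list in Terc-/- samples, with 52 of 57 members higher and a mean difference of 0.31 (camera adjusted p = 4.7e-10). This call was lost with an estimated correlation (adjusted p = 0.646). The members of smallest p were Lgals3bp (1.87 ± 0.53, SE), the immunoproteasome subunit Psmb8 (0.48 ± 0.15) and Oasl2 (0.69 ± 0.23). The list's mean deviation was 0.40, 0.35 and 0.33 in Terc-/- replicates 1, 5 and the averaged 2 and 6, and -0.15 in both replicates 3 and 4, while WT samples lay between -0.38 and 0.03. Glycolysis and hypoxia genes also rose, with 22 of 32 higher (mean 0.13, adjusted p = 0.0159, and adjusted p = 0.646 with an estimated correlation), including the glucose transporter Slc2a1 (0.38 ± 0.12). That call ended without WT replicate 4 (adjusted p = 0.0818), without Terc-/- replicate 5 (0.0743) or without Terc-/- replicate 1 (0.0531, mean 0.09).

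Cell division genes fell as lists. Among G2/M and mitosis genes, 41 of 43 were lower (mean -0.29, adjusted p = 2.4e-09), with Ndc80 (-0.51 ± 0.15, SE) and Ncapg (-0.50 ± 0.15) of smallest p, and among genes of DNA replication and G1/S 41 of 48 were lower (mean -0.19, adjusted p = 1.4e-07). Both calls were lost with an estimated correlation (adjusted p = 0.646). Cdc45, Gins3 and the DNA ligase Lig1 (-0.39 ± 0.10) passed when adjusted over the list alone (adjusted p = 0.0150, 0.0185 and 0.0388). Terc-/- replicate 1 had the lowest mean deviation of G2/M genes (-0.67, against -0.11 to 0.18 in the other Terc-/- samples), and without it the list means were -0.16 for G2/M and -0.12 for replication.

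Oxidative phosphorylation genes fell slightly (53 of 68 lower, mean -0.09, adjusted p = 3.1e-04), with Cyc1 (-0.39 ± 0.09, SE) of smallest p, as did genes of the DNA damage response (47 of 64 lower, mean -0.09, adjusted p = 0.0135), led by Chek2. With an estimated correlation the adjusted p was 0.646 for both. The first call ended without Terc-/- replicate 5 (adjusted p = 0.0524), and the second without it (0.0743), without WT replicate 3 (0.0626) or without WT replicate 4 (0.0818).

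The p53 targets divided evenly, with 25 of 49 higher and 24 lower, a median of 0.01 and a mean of 0.13 (adjusted p = 0.0893, and 0.646 with an estimated correlation). Phlda3 alone passed when adjusted over the list alone (adjusted p = 0.00890), and Dyrk3 (0.86 ± 0.31, SE) and Trp53inp1 (0.75 ± 0.28) followed it. Among the genes fixed in advance, Mdm2 averaged 11.67 against 11.39 (0.27 ± 0.15, and 0.18 without WT replicate 1), Foxo3 7.77 against 7.27 (0.50 ± 0.17), Kit 12.91 against 12.52 (0.39 ± 0.16) and Hoxa9 10.18 against 10.54 (-0.36 ± 0.24, with -0.22 without Terc-/- replicate 1 and -0.23 without WT replicate 4). Cdkn1a (-0.14 ± 0.52), Meis1 (-0.10 ± 0.31) and Xist (-0.20 ± 0.85) differed by less than their error, and the sign of each turned under some alternatives.

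None of the 10 cell type marker lists passed. Mature neutrophil genes came closest, with 19 of 26 lower a mean of -0.53 and a median of -0.28 (adjusted p = 0.0990), including Camp (-1.82 ± 0.65, SE) and Olfm4 (-1.64 ± 0.57). The mean was -0.32 without Terc-/- replicate 4 and -0.86 without Terc-/- replicate 3. In the granulocyte-macrophage progenitor list, Serpinb1a, an inhibitor of neutrophil proteases, was 0.50 ± 0.10 (SE) higher and passed when adjusted over the list alone (adjusted p = 0.0159), while the list itself did not (0.818, with a mean of -0.11 although camera's direction was up). That mean was -0.02 without Terc-/- replicate 4 and -0.06 without WT replicate 2. The adjusted p was 0.696 for telomere maintenance genes, 0.422 for FOXO targets, 0.409 for apoptosis genes, 0.386 for MLL fusion targets and 0.465 for stem cell genes. Medians were -0.01 and means positive for telomere maintenance genes (0.01), FOXO targets (0.08) and MLL fusion targets (0.07). Single samples moved these small means. For FOXO targets the mean was 0.03 without Terc-/- replicate 1, 0.04 without WT replicate 3, 0.13 without WT replicate 1 and 0.14 without the averaged Terc-/- replicates 2 and 6. For MLL fusion targets it was -0.0014 without WT replicate 2, 0.03 without Terc-/- replicate 5 and 0.13 without the averaged Terc-/- replicates 2 and 6, and for telomere maintenance genes it lay between -0.0052 and 0.03 over all omissions of 1 sample. In all, 6 of 30 lists passed camera at the preset correlation, and none did with an estimated correlation or by fry (smallest adjusted p = 0.646 and 0.476, with 1 and 0 lists at an unadjusted p under 0.05). Lists past the threshold numbered 3 without Terc-/- replicate 5 and 10 without the averaged Terc-/- replicates 2 and 6. Adjusted over the list alone, 5 genes passed, against 0 when adjusted over all genes. Exact permutation tests of the list means gave p = 0.0476 for DNA replication, the smallest, p = 0.0635 for G2/M, p = 0.0794 for interferon and p = 0.0873 for p53 targets (n = 5 and 5), each with an adjusted p of 0.408 over the 30 lists.

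**Figure D2:**
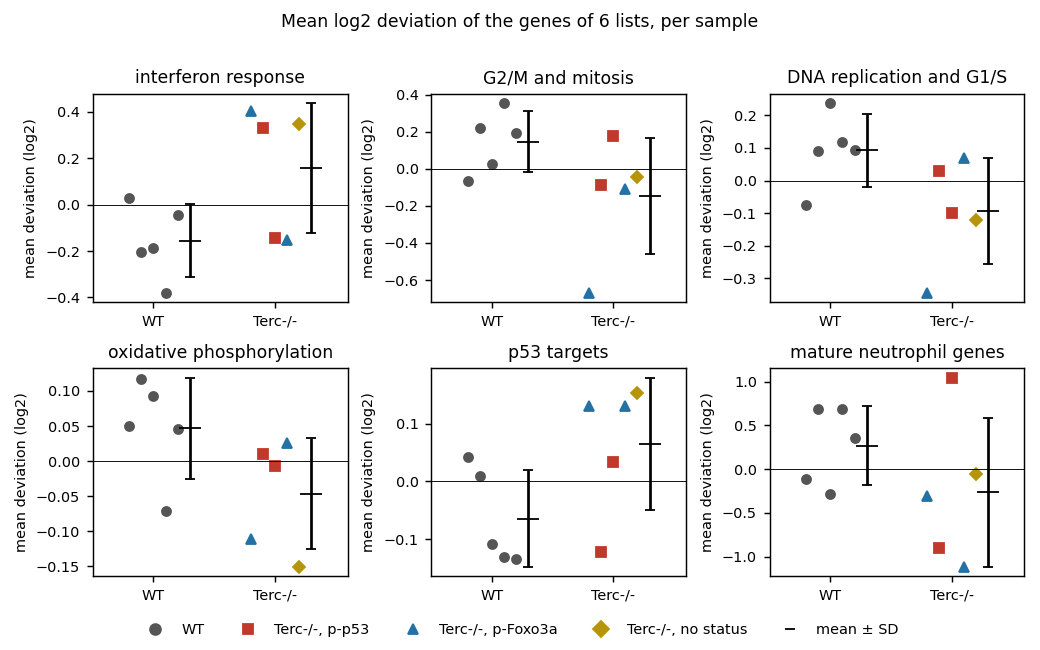
Mean deviation (log2) of the genes of 6 lists from their overall means in each sample, by group, with bars for the mean and SD of the group. Interferon genes lie above 0.3 in 3 Terc-/- samples and below 0 in the other Terc-/- samples, and G2/M genes are lowest in 1 p-Foxo3a sample at -0.67.

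The labelled phosphorylation status divides the Terc-/- samples, and each kind was compared with the 5 WT samples. In the 2 p-p53 samples Rap1gap, which inactivates the small GTPase Rap1, was not above background (6.31 ± 0.05, SD, n = 2), whereas it averaged 8.96 ± 0.45 (SD, n = 5) in WT, at least 5.23-fold higher there. Lrig3 (-1.67 ± 0.40, SE, above background in 1 of 2) and Brip1 (-0.76 ± 0.13) were lower in p-p53 samples, while Them7 (1.38 ± 0.23) was higher. Interferon genes rose as a list (51 of 57 higher, mean 0.25, adjusted p = 3.4e-05) and genes of DNA replication fell (39 of 48 lower, mean -0.13, adjusted p = 0.00181), both with an adjusted p of 0.888 with an estimated correlation. Genes of the unfolded protein and integrated stress response fell too (25 of 36 lower, mean -0.17, adjusted p = 0.0262), with Mthfd2 (-0.87 ± 0.26) and Atf5 (-0.50 ± 0.16) of smallest p, as did MYC targets (31 of 42 lower, mean -0.11, adjusted p = 0.0497). These calls were lost with an estimated correlation as well (adjusted p = 0.888 for both). The p53 targets did not rise as a list in p-p53 samples (25 of 49 higher and 24 lower, mean 0.02, camera adjusted p = 0.727).

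No gene passed in limma (312 with an unadjusted p under 0.05, fewer than the 594 expected by chance), and none passed when adjusted over the list alone. With all arrays as separate samples, 1 gene passed, Rap1gap (adjusted p = 0.0266). Single samples decided most of these values. Leaving out 1 p-p53 sample left 1, which was assumed to vary like the other groups. Adjusted p-values and gene counts of such fits therefore describe 1 sample. Without the averaged replicates 2 and 6 the interferon mean was 0.01 (adjusted p = 0.986), the stress response mean -0.05 (0.934), the replication mean -0.19 and the MYC mean -0.17 (0.0542), and 1 gene passed, Pcdh7 (3.16), named after its value was seen. Without replicate 3 the replication mean was -0.06 (adjusted p = 0.432), the MYC mean -0.04 (0.526), the interferon mean 0.49 and the stress mean -0.29, and 15 genes passed. Replication also lost its call without WT replicate 3 (0.0737), stress genes without WT replicate 3 (0.168), WT replicate 2 (0.0690) or the array of Terc-/- replicate 6 (0.0558), and MYC targets without WT replicate 1 (0.0815), WT replicate 3 (0.525, mean -0.04), WT replicate 6 (0.0509) or Terc-/- replicate 6 (0.0785). The number of lists was 2 without WT replicate 3, without Terc-/- replicate 6 or without the averaged replicates 2 and 6.

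In the 2 p-Foxo3a samples the GATA-type repressor Trps1 averaged 11.14 ± 1.00 (SD, n = 2), against 7.75 ± 0.76 (SD, n = 5) in WT, a difference of 3.39 ± 0.62 (SE) or 10.5-fold. The Trps1 difference was 2.68 without replicate 1 and 4.10 without replicate 4. Litaf (1.08 ± 0.19), Samsn1 (1.04 ± 0.17) and Phlda3 (1.22 ± 0.24) were also higher, and Ralgps2 (-1.89 ± 0.37), the phospholipase Plcb2 (-0.86 ± 0.13) and the pore-forming protein Gsdmd (-0.60 ± 0.12) were lower. G2/M and mitosis genes fell, with 42 of 43 lower (mean -0.53, adjusted p = 8.3e-16, and adjusted p = 0.621 with an estimated correlation), and 8 of them passed when adjusted over the list alone (adjusted p = 0.0486 each), including the mitotic kinase Plk1 (-1.07 ± 0.28) and the spindle factor Tpx2 (-0.90 ± 0.19). Replication genes (39 of 48 lower, adjusted p = 7.6e-05), mature neutrophil genes (22 of 26 lower, mean -0.98, adjusted p = 0.00768) and oxidative phosphorylation genes (47 of 68 lower, adjusted p = 0.0499) fell as well, each with an adjusted p of 0.621 with an estimated correlation. Interferon genes (44 of 57 higher, adjusted p = 4.1e-04), immediate early and heat shock genes (25 of 36, mean 0.44, adjusted p = 0.00585), glycolysis genes (23 of 32, adjusted p = 0.0285) and ribosomal protein genes (38 of 54, adjusted p = 0.0499) rose. These 4 calls were lost with an estimated correlation too (adjusted p = 0.621 for each). The p53 targets did not pass as a list (28 of 49 higher, mean 0.20, camera adjusted p = 0.0795).

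No gene passed in limma (smallest adjusted p = 0.374, with 1162 genes at an unadjusted p under 0.05), and 12 passed when adjusted over the list alone, among them Phlda3 and Dyrk3 of the p53 targets (adjusted p = 0.0266) and Igfbp4 (-2.88 ± 0.73, SE, adjusted p = 0.0430). Much of this rested on Terc-/- replicate 1, which had the lowest median correlation with other samples (0.972) and whose chromosomes 6 and 16 lay 0.36 and 0.35 above their level in the other samples. Of the 24 named genes, 8 lie on chromosomes 2, 6 or 16. These chromosomes hold 564, 359 and 236 of the 7068 genes in the chromosome scan, which leaves out dim genes. Ly6k, Sla, Trps1, Atp6v1c1 and Gsdmd, also among the 24, lie on chromosome 15, which holds 281 genes of the scan. Its median in replicate 1 was -0.014, so named genes also gather on a chromosome without such a shift. Dennd5b, Samsn1, Litaf, Plcb2 and Acp2 differed from WT in the direction of their chromosome's shift in replicate 1 (chromosome 2 at -0.16). Slc6a13, Cass4 and Ntng2 differed in the direction opposite to their whole chromosome's median. On chromosome 2 the shift lay mainly in a run of 150 genes (median -0.68, against -0.07 in the other 414). Which of the named genes lie in that run is not given here. In replicate 4 the medians of chromosomes 2, 6 and 16 were 0.011, -0.011 and -0.015. Samsn1 was 13.20 there (WT mean 12.17), Litaf 13.17 (12.32), Dennd5b 8.20 (7.08), Plcb2 10.86 (11.51) and Acp2 8.89 (9.45). The differences of these genes were therefore not confined to replicate 1. They were chosen for small p with both samples in the fit, and whether the shifts added to their differences was not tested. Without replicate 1 the interferon and replication lists were no longer called (means 0.00 and -0.02, adjusted p = 0.946 for both), nor were oxidative phosphorylation (0.872, mean -0.02), glycolysis (0.245, mean 0.09), ribosomal (0.0888) and immediate early genes (0.0557). The G2/M mean was -0.25 without it, 4 lists passed, and 1 gene passed, the granule enzyme Mpo (-1.92), named after its value was seen. Without replicate 4, the means were -0.81 for G2/M, -0.44 for replication, 0.56 for interferon and -0.16 for oxidative phosphorylation genes. Neutrophil (mean -0.57), ribosomal (mean 0.04), immediate early and glycolysis genes (mean 0.32) were then not called. Leaving out either replicate left 1 p-Foxo3a sample, which was assumed to vary like the other groups. Adjusted p-values and gene counts of such fits therefore describe 1 sample. Without the averaged WT replicates 5 and 6, immediate early genes were not called either (0.0501), and 5 lists passed.

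Ribosomal protein genes (mean 0.06) and oxidative phosphorylation genes (mean -0.09) passed narrowly in p-Foxo3a samples, both with an adjusted p of 0.0499. Ribosomal genes did not pass without WT replicate 3 (0.0939), WT replicate 4 (0.138, mean 0.03), WT replicate 5 (0.0736) or the averaged WT replicates 5 and 6 (0.109). Oxidative phosphorylation genes did not pass without WT replicate 1 (0.0725), replicate 2 (0.113), replicate 3 (0.101), replicate 5 (0.0547), replicate 6 (0.0570) or the averaged 5 and 6 (0.0732). Omitting p-p53 samples, which enter through the pooled spread, also took both past 0.05, with 0.0628 without replicate 3 or the averaged replicates 2 and 6, 0.0529 without the array of replicate 2 and 0.0511 without that of replicate 6.

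The difference between p-p53 and p-Foxo3a samples was tested directly, 2 samples against 2 with the spread of the WT samples in the fit, and is given as p-p53 minus p-Foxo3a. G2/M genes were higher in p-p53 samples (41 of 43, mean 0.43, adjusted p = 1.4e-11, and adjusted p = 0.672 with an estimated correlation), with Nusap1 (1.12 ± 0.38, SE) and Plk1 (0.86 ± 0.33) among those of smallest p. Mature neutrophil genes (22 of 26, mean 0.78, adjusted p = 0.0195) and granulocyte-macrophage progenitor genes (22 of 31, mean 0.31, adjusted p = 0.0383) were also higher, the former with Chil3 (2.58 ± 1.05). With an estimated correlation their adjusted p was 0.844 and 0.672. Immediate early and heat shock genes were lower in p-p53 samples (32 of 36, mean -0.58, adjusted p = 2.8e-05), with Zfp36l1 (-3.19 ± 1.36) and Junb (-0.68 ± 0.31), as were ribosomal protein genes (41 of 54, mean -0.09, adjusted p = 0.0187), MYC targets (32 of 42, mean -0.13, adjusted p = 0.0305) and FOXO targets (24 of 35, mean -0.26, adjusted p = 0.0383), including Foxo1 (-0.57 ± 0.22) and Gabarapl1 (-1.11 ± 0.53). With an estimated correlation the adjusted p was 0.844 for MYC targets and 0.672 for the other 3 of these lists. The p53 targets did not pass as a list (35 of 49 lower in p-p53 samples, mean -0.18, camera adjusted p = 0.127). Rap1gap was at least 7.27-fold and Grb7 at least 2.06-fold higher in p-Foxo3a samples, both being below background in the 2 p-p53 samples, and Trps1 was 11.6-fold lower in p-p53 samples (-3.54 ± 0.74). The Trps1 difference was -2.83 without replicate 1, -4.25 without replicate 4, -4.35 without replicate 3 and -2.73 without the averaged replicates 2 and 6, and Rap1gap was 10.10 in replicate 1 and 8.77 in replicate 4. Grb7 was 8.01 in replicate 1 and 7.22 in replicate 4.

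No gene passed in limma (smallest adjusted p = 0.596, with 610 genes at an unadjusted p under 0.05), and Bcl11b (-1.89 ± 0.46, SE) passed when adjusted over the T and NK list alone (adjusted p = 0.0431). Each omission of a Terc-/- sample left 1 sample of its kind, which was assumed to vary like the other groups. Adjusted p-values and gene counts of such fits therefore rest on 1 sample of that kind. Without Terc-/- replicate 3, 12 genes passed, the neutrophil mean turned to -0.19 (adjusted p = 0.277), ribosomal genes (0.213, mean -0.05), MYC targets (0.258, mean -0.06) and progenitor genes (0.0989) lost their calls, 4 lists passed, and the immediate early mean was -0.998. Without replicate 4, 29 genes passed, MYC targets turned to a mean of 0.14 (adjusted p = 0.163), neutrophil (0.716, mean 0.38), progenitor (0.642, mean 0.13) and ribosomal genes (0.163) were not called, and the G2/M mean was 0.71. Without the averaged replicates 2 and 6 immediate early genes had a mean of -0.16 (adjusted p = 0.474), FOXO targets (0.474, mean -0.16) and progenitor genes (0.130) were not called, the means were 1.75 for neutrophil genes and -0.19 for MYC targets, and 1 gene passed, Pcdh7. Without replicate 1 the G2/M mean was 0.15 (adjusted p = 0.0233), FOXO targets were not called (0.447), the means were 1.18 for neutrophil genes, 0.49 for progenitor genes and -0.39 for MYC targets, and 1 gene passed, Mpo. FOXO targets also lost their call without WT replicate 4 (0.0654).

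The p-p53 and p-Foxo3a differences from WT correlated across the 11889 genes at r = 0.350, with the same sign in 61.9% of genes, which are not independent replicates. Unchanged groups simulated against the same WT samples gave r = 0.283 and 59.2%, and the covariance was 0.0294 against 0.0212 simulated. When each comparison used different WT samples, r averaged 0.141 over 20 splits, from -0.10 to 0.30. With the shared WT samples, r was 0.112 without Terc-/- replicate 1, 0.132 without Terc-/- replicate 3 and 0.472 without WT replicate 1. Unchanged groups were not simulated for these reduced sets of samples.

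**Figure D3:**
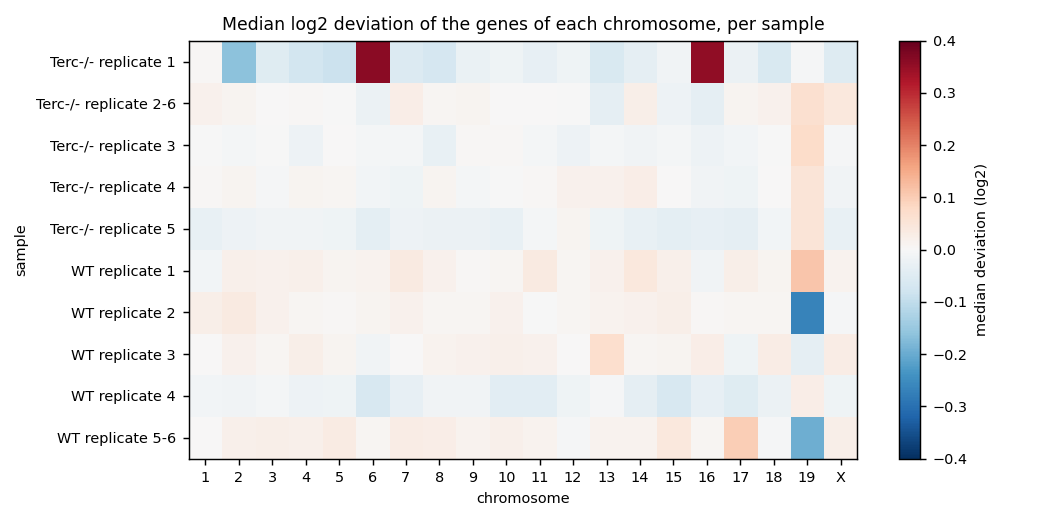
Median deviation (log2, colour) of the genes of each chromosome (horizontal axis) from their medians over samples, in each of the 10 samples (vertical axis). Chromosomes 6 and 16 of Terc-/- replicate 1 stand at 0.36 and 0.35, and chromosome 19 is at -0.27 and -0.19 in WT replicate 2 and the averaged WT replicates 5 and 6.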

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

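The tests of brightness, of a few genes and of gain or loss of chromosome material were chosen after the chromosome medians had been seen. Of 164 groups of samples examined, 12 had a sample far from the others, against 8.2 by chance (about 1 group in 20). Phlda3 was 6.85 in Terc-/- replicate 3, below the 7.60 to 7.85 of the other Terc-/- samples. Coa4, a mitochondrial assembly factor, was 10.77 in Terc-/- replicate 4, above the 10.29 to 10.38 of the others. Mdm2 was 11.23 in the averaged Terc-/- replicates 2 and 6, below the 11.73 to 11.83 of the others. The mean deviation of mitochondrial biogenesis genes was 0.20 in WT replicate 3, against -0.09 to -0.03 in the other WT samples. MLL fusion targets stood at -0.33 in WT replicate 2, against -0.01 to 0.08. Immediate early and heat shock genes stood at -0.64 in the averaged Terc-/- replicates 2 and 6, against 0.14 to 0.40 in the other Terc-/- samples, and in WT the averaged replicates 5 and 6 were lowest, at -0.63. Chromosome medians stood apart in Terc-/- replicate 1 for chromosomes 2 (-0.16), 5 (-0.087), 6 (0.36), 16 (0.35) and 19 (-0.0037, against 0.05 to 0.07), and in WT replicate 4 for chromosome 10 (-0.043).

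The p-p53 and p-Foxo3a samples, 2 of each, differed in 7 lists by camera, given as p-p53 minus p-Foxo3a. The mean difference was 0.43 for G2/M and mitosis, 0.78 for mature neutrophil genes and 0.31 for granulocyte-macrophage progenitor genes. It was -0.58 for immediate early and heat shock genes, -0.26 for FOXO targets, -0.13 for MYC targets and -0.092 for ribosomal proteins. None of these passed with an estimated correlation (adjusted p = 0.672 or 0.844).

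In Terc-/- replicate 1, genes of chromosomes 6 and 16 stood 1.28-fold above their level in the other samples, and a run of 150 genes of chromosome 2 from Cytip to Cep152, which holds the myeloid regulator Spi1 and whose limits were chosen after its values were seen, had a median of -0.68. Sets of genes of other chromosomes matched on brightness to chromosome 6 reached a median of at most 0.0349, which argues against brightness or scaling of the array. The less variable genes of both chromosomes were shifted by 0.37, which argues against a different mix of cells. Of all genes of both chromosomes, 82.2% lay above their median over samples, so the shift was not confined to a few genes. This share mostly follows from the chromosome medians that prompted the test and adds little to them. On chromosomes 6 and 16, 100% of windows of 50 neighbouring genes lay above 0.1, so a candidate explanation is gain of these chromosomes in that leukaemia. The run on chromosome 2 was not tested in these ways, DNA was not analysed here, and no explanation by the study's groups was tested.

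Chromosome 19 genes were lower in WT replicate 2 (median -0.27, 87.1% of 271 genes below their median over samples) and in the averaged WT replicates 5 and 6 (-0.19, 85.6%) than in the other samples. The share of 85.6% means that the shift was not confined to a few genes, but it mostly follows from the median that prompted the test. A median of -0.18 among the less variable genes in the less shifted sample argues against a different mix of cells. In that sample 100% of windows on the chromosome lay below -0.05. Because values are relative to the median over samples, lower copy number in these WT leukaemias and higher copy number in the others are both candidate explanations. No explanation by the study's groups was tested.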

How the results depend on the processing

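The 12 arrays as separate samples, cyclic loess, normexp with an offset of 50, the omission of genes of chromosomes 2, 6, 16 and 19 and the omission of both arrays of a near-identical pair were chosen after seeing the data. In all 4 comparisons no gene passed in limma without the dim-probe filter, with either stricter filter, with the mean of a gene's probes, each probe by itself, a trended robust variance, array weights, the replicate block over 12 arrays, cyclic loess, normexp or the omission of 4 chromosomes. At an unadjusted p under 0.05 these gave 728 to 1266 genes for Terc-/- against WT, 246 to 754 for p-p53 against WT, 754 to 1553 for p-Foxo3a against WT and 343 to 899 for p-p53 against p-Foxo3a, the last including the samples of the 2 kinds alone. Adjusted over the list alone, 5 genes passed for Terc-/- against WT, 12 for p-Foxo3a against WT and 1 for p-p53 against p-Foxo3a, because fewer genes were tested. As separate samples, the 12 arrays gave 1 gene for p-p53 against WT. Camera with an estimated correlation and fry each gave 0 lists in every comparison, with at most 1 list at an unadjusted p under 0.05. The replicate block was fitted over the 12 arrays as separate samples, so it changed 2 choices at once. It gave 7 lists for p-p53 against WT, 4 for p-p53 against p-Foxo3a and r = 0.170 for the agreement of the p-p53 and p-Foxo3a changes, where the 12 arrays without the block gave 4, 5 and 0.286. The samples of these 2 kinds alone gave 4 lists. The cause was not tested. Replicate numbers pair no samples, since the deviations of WT and Terc-/- samples of the same number correlated at -0.22 to 0.15.

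Leaving out arrays gave 0 to 1 genes and 3 to 10 lists for Terc-/- against WT, 0 to 15 genes and 2 to 6 lists for p-p53 against WT, 0 to 260 genes and 4 to 8 lists for p-Foxo3a against WT, and 0 to 29 genes and 4 to 7 lists for p-p53 against p-Foxo3a. The agreement was r = 0.112 to 0.472. Where 1 sample of a kind was left, that sample was assumed to vary like the other groups.

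List calls that ended (adjusted p) were, for p-p53 against WT, the stress response without the 4 chromosomes (0.142) and MYC targets with 12 arrays (0.131). For p-Foxo3a against WT, ribosomal and oxidative phosphorylation genes ended with the replicate block over 12 arrays (0.156 and 0.633, against 0.0408 and 0.0434 for 12 arrays without the block), cyclic loess (0.168 and 0.0622) and normexp (0.0597 for both), and ribosomal genes also without the 4 chromosomes (0.0506). For p-p53 against p-Foxo3a, FOXO targets (0.469), progenitor (0.641) and ribosomal genes (0.192) ended with the block over 12 arrays (0.0390 each without the block), and neutrophil genes ended over 12 arrays with it (0.261) and without it (0.207). The samples of the 2 kinds alone ended FOXO targets (0.0807), progenitor (0.0818) and neutrophil genes (0.0544). FOXO targets also ended without the filter (0.0705) and with cyclic loess (0.0502), ribosomal genes with cyclic loess (0.120), MYC targets with 12 arrays (0.0568) and without the 4 chromosomes (0.0512), and progenitor genes without the 4 chromosomes (0.0816).

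Of 2677 recomputed values of 103 named gene values, 2649 kept their direction and side of the threshold, 17 newly passed and 11 reversed. The reversed values were differences of Terc-/- against WT in genes that passed no test. Cdkn1a reversed with array weights (0.15), Meis1 with the mean of its probes (0.14), each probe by itself (0.48) and array weights (0.08), and leaving out arrays gave -0.36 to 0.33 for Cdkn1a, -0.24 to 0.13 for Meis1 and -0.71 to 0.53 for Xist. The cause was not tested. Log2 of the raw signal without background correction, an offset of 50 on the raw signal and median scaling were not run because the raw columns match no sample, and no slide is given for a slide block. Signal over background limits dim genes such as Phlda3 in WT, whose folds are understated.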

Other observations

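The tests of G2/M genes without Terc-/- replicate 1 and of the splits for genes past the threshold were chosen after their results had been seen. The Y-linked gene Eif2s3y was 9.51 in Terc-/- replicate 5 and at most 6.41 in the other 9 samples, and Kdm5d was 7.21 there against 6.12 to 6.47. Xist, the RNA of the inactive X chromosome, was 11.72 in the same sample, 8.93 in Terc-/- replicate 3, 10.02 in WT replicate 1 and 11.68 to 13.55 in the others. Mpo, an abundant granule enzyme of myeloid progenitors, averaged 15.64 in WT and 14.66 in the p-Foxo3a samples. The difference of p-Foxo3a from WT samples was -1.92 without Terc-/- replicate 1, so Terc-/- replicate 4 carried the lower mean. The WT mean of Mpo lies close to the highest value on the arrays (15.95). Mpo and these Y-linked genes were chosen after their values were seen.

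G2/M and mitosis genes were lower in Terc-/- samples by a mean of -0.29 (41 of 43 genes), with an exact permutation p of 0.0635 for the groups of 5 and 5 samples. A single sample and a different share of maturing neutrophils were examined as explanations, and no other cause was tested. Without Terc-/- replicate 1 the mean was -0.16, between the values set for 1 sample carrying the shift and for a shift shared by the group, so this stays open. With the score of 30 mature neutrophil genes (26 measured, 2 held by another list) as a covariate it was -0.19, but more maturing, non-dividing cells would need higher neutrophil genes in Terc-/- samples, and 19 of 26 were lower (mean -0.53, adjusted p = 0.0990). That mean was -0.32 without Terc-/- replicate 4, -0.37 without the averaged replicates 2 and 6 and -0.86 without replicate 3, whose score of 1.04 was the highest of all samples. The neutrophil mean stayed negative under every omission of 1 sample, which goes against this explanation. The neutrophil score was highest in Terc-/- replicate 3 (1.04), WT replicates 4 and 2 (0.69 each) and the averaged WT replicates 5 and 6 (0.36). These samples also had the highest G2/M scores (0.18, 0.35, 0.22 and 0.19). The slope on the covariate was thus positive, whereas more non-dividing cells would lower G2/M genes, which also goes against this explanation. The samples varied widely, with an exact permutation p of 0.238 for the neutrophil list, and the slope was not tested, so the explanation is not excluded. Abundant neutrophil genes averaged 15.60 in WT and 15.32 in Terc-/- samples for S100a8 and 15.08 and 13.26 for Camp, although the sort for lineage-negative cells would remove mature neutrophils.

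From 100 splits of the 10 samples into 5 and 5, the real one included, chance cannot be excluded for 2 counts of Terc-/- against WT. At an unadjusted p under 0.05 the real split gave 883 genes and the highest other split 1326, and 15 of the 100 splits, with the real one, gave at least 883. For lists past the threshold the real count was 6 and the highest other 12, and 56 of the 100 splits, with the real one, gave at least 6. For genes past the threshold the real count was 0, which 100 of 100 splits reach by definition, so that comparison says nothing about chance (the highest other was 15).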
